A study of Mus musculus with 10 samples.

How the data were processed

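Total RNA of primary B-cell lymphomas from Emu-myc mice lacking Suv39h1 was measured on 10 Affymetrix mouse expression arrays. The cells carried a retroviral Bcl2 and grew on irradiated NIH 3T3 fibroblasts, per the labels' protocols. Each of 5 lymphomas (named lymphoma_5783, lymphoma_7890, lymphoma_9250, lymphoma_1032 and lymphoma_4936) gave an untreated array and an array of cells treated with Adriamycin (ADR, doxorubicin) at 0.05 µg/ml for 5 days. The untreated group and the ADR group therefore hold 5 arrays each, and the lymphoma number pairs them.

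The deposited table holds log2 signals, 1 value per probe set and array, which the authors made with RMA and Partek, per the submitters' processing notes. Versions, the RMA settings and the log base are not given in the sources used here; the range of the values is that of log2 RMA signals, and they were read as such. No further background correction or normalization was applied in the main setting. The array medians lay between 4.43 and 4.50 on 9 arrays and at 4.15 on the ADR array of lymphoma_1032, so that the array distributions were not identical. The number of arrays, 5 per group, limits the precision of each value.

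Of 45101 probe sets, 64 were Affymetrix controls, 34945 had exactly 1 gene symbol in the platform annotation, 932 had several symbols or gene IDs, and 9160 were unnamed there. Gene IDs of 34741 of the single-symbol probe sets were found in the RefSeq table of the mouse reference, and 0 symbols needed replacement. These probe sets covered 18193 genes. A gene was represented by its probe set with the highest mean over the 10 arrays. Genes above the median of the whole table, 4.43, on at least 5 of 10 arrays were tested, which left 11472 genes. Suv39h1 and Trp53, both on the list of genes to be named, are not analysed here because no probe set was named for them, so the genotype could not be checked from the arrays.

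Changes were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the lymphoma as a block and the difference of ADR minus untreated as the coefficient. P-values are two-sided, and adjusted p is Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Same-numbered samples came from the same animal's lymphoma, per the labels. Each array correlated best with the array of its own lymphoma, and the deviations from the group means correlated within pairs between 0.51 and 0.79 across genes. The means ± SD given below are over 5 lymphomas.

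Before the data were examined, 24 lists of genes and 7 lists of cell type markers were fixed, 795 entries in all, of which 57 had no named probe set. The 27 lists with at least 5 tested members were tested with camera of limma, a competitive test that compares a list with the other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 27 lists. Camera was also run with the correlation estimated from the data and on ranks. With an estimated correlation camera also takes its p from the few residual degrees of freedom of the fit. A call lost there can therefore reflect the small number of pairs, correlation among the genes above the preset, or both. Fry, which asks whether a list's genes move one way on balance without comparing them with other genes, was added after the data were seen. The fibroblast list and the 3' to 5' control probe difference were tested with exact sign-flip permutation tests over the 5 pairs, two-sided, whose smallest possible p is 0.0625.

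The genes to be named were to be the largest changes past the threshold, the largest members of each list past the threshold, and a fixed set of 12 genes. As no gene passed, other genes were named after their values were seen: for each list the members that moved in the list's direction in the most lymphomas, ordered by p, and for all genes those with the smallest p among genes with 1 sign in all 5 lymphomas. A few further genes were named for their levels.

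The fit was tested on simulated data with the observed spread and 11472 genes. Of 50 genes changed by 0.5 on the log2 scale 18% were recovered, of 50 changed by 1 60%, of 50 changed by 2 98% and of 50 changed by 3 100%. Of 11272 unchanged genes 9 were called. A simulated list shifted by 0.5 was called and 0 of 26 unshifted lists were. The simulation drew genes independently, which real genes are not. The alternatives were no block, no filter on low genes, a stricter filter at the 70th percentile, the mean of all probe sets of a gene, another quantile normalization, centring of each array, a trended and robust prior, array weights and leaving out each lymphoma. Chosen after seeing the data were fry and the omission of lymphoma_5783 and lymphoma_1032 or of lymphoma_1032 and lymphoma_4936 together, and camera with an estimated correlation in each omission and in all of these settings but no block and the trended prior. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.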

Results

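The question named by the series is what Adriamycin, a DNA-damaging drug that drives Bcl2-protected Emu-myc lymphomas into senescence, does to the transcripts of such lymphomas when they lack Suv39h1, a histone H3 lysine 9 methyltransferase. RNA levels of 11472 genes were compared between untreated cells and cells treated for 5 days with 0.05 µg/ml ADR, in 5 lymphomas with 1 array per condition each. Levels are log2 array signals and changes are log2 differences of ADR minus untreated within a lymphoma. Suv39h2, the paralog of the deleted gene, had a signal of 6.12 ± 0.43 (SD, n = 5) in untreated cells and of 5.86 ± 0.78 in ADR cells, a change of -0.26 that was 0.03 without lymphoma_1032.

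No gene passed the threshold: 0 of 11472 genes rose and 0 fell in the paired limma fit, also at 2-fold or more, and the smallest adjusted p was 0.551. At an unadjusted p below 0.05 there were 973 genes, 455 higher and 518 lower in ADR, against 573.6 expected by chance. The balance of the directions turned with the lymphomas used. Without lymphoma_1032, 551 were higher and 289 lower, and without lymphoma_4936, 493 and 953. The average change reached 2-fold in 53 genes, 31 of them higher and 22 lower, whatever their p. The change had 1 sign in all 5 lymphomas for 1089 genes, 9.49% of those tested, where independent signs give 6.25%; with the sign of lymphoma_4936 turned it was 1549 genes, 13.5%. The smallest p-values among these belonged to Rasgrp2, an exchange factor for small GTPases, with a mean change of -0.92 ± 0.15 (SD, n = 5), and to Zfpm1, the GATA cofactor FOG1, with -0.78 ± 0.13. Csrp2 had a change of -1.26 ± 0.46 and Mgarp, a mitochondrial protein, of -1.64 ± 0.70. In the other direction, Lrrc28 had a change of 1.40 ± 0.67, the dipeptidyl peptidase gene Dpp7 of 1.16 ± 0.55 and App of 0.96 ± 0.45. The lysosomal phospholipase family gene Pld4 had a change of 1.17 ± 0.59 and Cd274, which encodes PD-L1, of 0.68 ± 0.29. These genes were chosen after their values were seen, and none passed the threshold.

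On average over each list, genes of cell division had lower signals with ADR in lymphoma_5783, lymphoma_7890, lymphoma_9250 and lymphoma_1032 and higher signals in lymphoma_4936. In the G2 and mitosis list, 48 of 50 tested members were lower on average, with a list mean of -0.48 ± 0.70 (SD, n = 5). The list changed by -1.14 in lymphoma_5783, -0.55 in lymphoma_7890, -0.59 in lymphoma_9250, -0.83 in lymphoma_1032 and 0.69 in lymphoma_4936. In lymphoma_5783 and lymphoma_1032, which had the lowest values, the 17 tested macrophage markers changed by 1.21 on average. The 5 macrophage markers that the filter left out changed by -1.83 and -0.32 there. Mki67, the proliferation marker Ki-67, had a signal of 10.36 ± 0.50 in untreated and of 9.50 ± 0.65 in ADR cells, a change of -0.85 ± 0.84. Kif11, a spindle motor, had a change of -0.93 ± 0.90, and Cenpa, the centromeric histone, of -0.80 ± 0.38 with a lower signal in all 5 lymphomas. In the S phase list 41 of 42 members were lower on average, with a mean of -0.30 ± 0.62, among them Slbp, the histone mRNA binding protein, at -0.42 ± 0.31 and Dtl at -0.52 ± 0.67, which was -0.31 without lymphoma_5783 and -0.78 without lymphoma_4936. Of the homologous recombination and checkpoint list 18 of 20 members were lower, with a mean of -0.30 ± 0.52, including Brca2 at -0.60 ± 0.40 and Fanci at -0.58 ± 0.54. Over all genes tested 0 members of these lists rose or fell, and adjusted over the list alone 0 passed. Camera placed the lists below the other genes, with adjusted p = 1.52e-11 for G2 and mitosis, 1.9e-05 for S phase and 0.00185 for homologous recombination. With an estimated correlation the calls were lost, with adjusted p = 0.619, 0.664 and 0.664. Without lymphoma_4936 the list means were -0.78, -0.57 and -0.52, and without lymphoma_5783 they were -0.32, -0.17 and -0.21, with adjusted p = 0.0539 for S phase and 0.059 for homologous recombination in camera.

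Targets of p53 were higher with ADR, most in lymphoma_7890, lymphoma_9250 and lymphoma_5783. Of 27 tested members 24 were higher on average, and the list mean was 0.40 ± 0.34 (SD, n = 5). The list changed by 0.81 in lymphoma_7890, 0.62 in lymphoma_9250, 0.45 in lymphoma_5783, 0.09 in lymphoma_4936 and 0.03 in lymphoma_1032. Phlda3, a repressor of Akt, had a change of 0.88 ± 0.41, Zmat3 of 0.94 ± 0.80, Ccng1 of 0.65 ± 0.49 and Cdkn1a, which encodes the cell cycle inhibitor p21, of 0.60 ± 0.43, each with a higher signal in all 5 lymphomas. Cdkn1a had a signal of 10.33 ± 1.33 in untreated and of 10.92 ± 1.13 in ADR cells. Over all genes 0 members passed, and adjusted over the list alone 1 did, Phlda3. Camera gave an adjusted p of 2.72e-10 and, with an estimated correlation, an adjusted p of 0.572. The list of CDK inhibitors and Rb family genes was not called (adjusted p = 0.874 in camera), with a mean of -0.09 ± 0.41 and a test direction opposite to that mean. In it, Cdkn1b had a change of -0.52 ± 0.61, which was -0.32 without lymphoma_1032, and Cdkn2a, the p16 and p19ARF locus, of -0.56 ± 1.43. The Cdkn2a value came from lymphoma_5783, where the change was -3.01, and without it the mean change was 0.06.

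Genes of the lysosome were higher with ADR in each of the 5 lymphomas, by 0.38 in lymphoma_5783, 0.24 in lymphoma_7890, 0.26 in lymphoma_9250, 0.31 in lymphoma_1032 and 0.11 in lymphoma_4936. Of 35 tested members 31 were higher on average, with a list mean of 0.26 ± 0.10 (SD, n = 5). The tested macrophage markers changed by 1.21 on average in lymphoma_5783 and in lymphoma_1032, which had the highest lysosome values. Over all genes 0 passed, and adjusted over the list alone 7 did. The peptidase gene Tpp1 had a change of 0.65 ± 0.23, Grn, the progranulin gene, of 0.50 ± 0.18, Lamp1, a lysosomal membrane protein, of 0.46 ± 0.18 and Ctsa of 0.42 ± 0.19. Glb1, the gene of the beta-galactosidase whose activity is used as a senescence stain, had a signal of 8.24 ± 0.20 in untreated and 8.54 ± 0.23 in ADR cells, and was higher in 4 of 5 lymphomas. Camera gave an adjusted p of 1.52e-11 for the list and, with an estimated correlation, an adjusted p of 0.48. The autophagy list, with a mean of 0.05 ± 0.15, was not called (adjusted p = 0.114 in camera), except with array weights (0.0276) and in the added omission of lymphoma_1032 and lymphoma_4936 (0.0276, with a mean of 0.13), where an estimated correlation gave adjusted p = 0.554 and 0.435.

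The senescence-associated secretory list was higher by 0.42 in lymphoma_5783 and by 0.56 in lymphoma_1032, and changed by 0.18 in lymphoma_7890, -0.10 in lymphoma_9250 and 0.02 in lymphoma_4936. Of 32 tested members 22 were higher on average, the list mean was 0.21 ± 0.27 (SD, n = 5), and 0 members passed over all genes or adjusted over the list alone. Mmp12, a macrophage elastase, had a change of 1.14 ± 0.76, and Fn1, which is also in the fibroblast list, of 0.66 ± 0.45. Il6 had signals of 10.99 untreated and 11.94 with ADR in lymphoma_1032 and of at most 6.26 on the arrays of the other lymphomas. Camera gave an adjusted p of 0.00143 for the list and, with an estimated correlation, an adjusted p of 0.572; without lymphoma_1032 the adjusted p was 0.347, with a mean of 0.13, and without the block it was 0.115. The tested macrophage markers changed by 1.21 on average in both lymphoma_5783 and lymphoma_1032 in the same comparison. NF-kB targets, with a mean of -0.15 ± 0.25, were not called (adjusted p = 0.0948 in camera). With the preset correlation they were called, with lower signals, without lymphoma_7890 (mean -0.26, adjusted p = 0.000501) or lymphoma_1032 (0.0241), with the stricter filter (0.00638) and after another quantile normalization (0.0185). With an estimated correlation these calls were lost, with adjusted p = 0.469, 0.717, 0.467 and 0.542. Without lymphoma_7890 the estimated correlation of this list was 0.0027, below the preset 0.01, so gene correlation was not the reason there. It was 0.15 without lymphoma_1032, 0.16 with the stricter filter and 0.14 after another quantile normalization. In these settings gene correlation may be part of the reason. In that list, Nfkbib had a change of -0.40 ± 0.17 and a lower signal in all 5 lymphomas.

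Markers of other cell types moved with ADR in some lymphomas. All 17 tested macrophage markers were higher on average, with a list mean of 0.55 ± 0.62 (SD, n = 5). Without the filter, which left out 5 of 22 members with a probe set, the mean was 0.30 (adjusted p = 0.000158 in camera, and 0.56 with an estimated correlation). The tested members changed by 0.13 in lymphoma_7890, -0.07 in lymphoma_9250 and 0.24 in lymphoma_4936, beside the 1.21 in the other lymphomas. The members left out changed by -1.83 in lymphoma_5783 and -0.32 in lymphoma_1032. Lyz2, lysozyme of macrophages, had a change of 0.96 ± 1.08 and Mpeg1 of 0.96 ± 0.75. Fibroblast markers, which the feeder cells could supply, were higher for 21 of 24 tested members, with a mean of 0.27 ± 0.39. They changed by 0.90 in lymphoma_5783, 0.42 in lymphoma_1032 and between -0.02 and 0.05 in the other lymphomas, and the exact sign-flip permutation test gave p = 0.188, where 0.0625 is the smallest possible. Lox, a collagen crosslinking enzyme, had a change of 0.68 ± 0.49. Of both lists 0 members passed over all genes or adjusted over the list alone. Camera gave an adjusted p of 3.05e-07 for macrophage markers and 0.000399 for fibroblast markers, and with an estimated correlation adjusted p = 0.572 and 0.619. Without lymphoma_5783 the fibroblast mean was 0.12 (adjusted p = 0.0507 in camera), and it was 0.46 with the stricter filter and 0.18 with the mean of all probe sets, both called with the preset correlation and not with an estimated correlation (adjusted p = 0.467 and 0.567). T-cell markers were not called (mean -0.04 ± 0.24, adjusted p = 0.641 in camera). Of the neutrophil, NK-cell, erythroid and endothelial lists only 3, 1, 2 and 3 members were tested, with mean changes of 0.59, -0.29, -0.07 and -0.12. The neutrophil members Mmp8, Mmp9 and Lcn2 changed on average by 1.82 in lymphoma_1032, 0.80 in lymphoma_5783 and between -0.19 and 0.41 in the other lymphomas. The 3' to 5' difference of the control probe sets for Gapdh and beta-actin, a sign of RNA integrity, had a change of 0.034 ± 0.052 (exact sign-flip permutation p = 0.188, n = 5).

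Metabolic lists moved in both directions. In the cholesterol biosynthesis list 19 of 20 members were lower on average, with a mean of -0.36 ± 0.46 (SD, n = 5) that was -0.17 without lymphoma_1032, where the list changed by -1.09, and the list was higher by 0.15 in lymphoma_5783. Hmgcs1 had a change of -0.54 ± 0.41 and Pmvk, a kinase of the mevalonate pathway, of -0.57 ± 0.53, which was -0.36 without lymphoma_1032. In the glycolysis list 13 of 17 members were lower, with a mean of -0.28 ± 0.36, among them the phosphofructokinase gene Pfkp at -0.77 ± 0.55. The glycolysis list changed by -0.62 in lymphoma_5783, -0.48 in lymphoma_9250, -0.52 in lymphoma_1032, 0.18 in lymphoma_7890 and 0.04 in lymphoma_4936. Of the Myc and ribosome biogenesis list 43 of 48 members were higher, with a mean of 0.16 ± 0.21, including Cad, of pyrimidine synthesis, at 0.34 ± 0.38 and the nucleolar Nop56 at 0.25 ± 0.21, which were 0.17 and 0.16 without lymphoma_1032. The pair of lymphoma_1032, whose ADR array had a median signal of 4.15 against 4.43 to 4.46 on the other ADR arrays, had a change of 0.51 in that list. Without it the mean was 0.07 and the adjusted p was 0.0868 in camera. Myc itself had a signal of 10.66 ± 1.08 untreated and 11.00 ± 0.76 with ADR. Over all genes, and adjusted over the list alone, 0 members of these lists passed. Camera gave adjusted p = 6.82e-06 for cholesterol biosynthesis, 0.00143 for glycolysis and 1.49e-07 for the Myc list, and with an estimated correlation adjusted p = 0.619 for each. Genes of the TCA cycle and oxidative phosphorylation were not called (mean 0.01 ± 0.13, adjusted p = 0.389 in camera), and neither were those of the unfolded protein and integrated stress response (mean -0.15 ± 0.26, adjusted p = 0.327 in camera, but 0.00791 with a mean of -0.26 without lymphoma_7890, where an estimated correlation gave adjusted p = 0.484), among which Asns, asparagine synthetase, had a change of -0.46 ± 0.27.

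Among chromatin and surface genes, the MHC class I list was higher in all 5 lymphomas, with a mean of 0.14 ± 0.11 (SD, n = 5) and 15 of 16 members higher, Tap2 at 0.22 ± 0.18 among them. The list of Wnt signalling and stem-cell genes had 8 tested members of 17 with a probe set, 6 of them higher, with a mean of 0.26 ± 0.22. It changed by 0.52 in lymphoma_5783 and 0.44 in lymphoma_1032, where the tested macrophage markers changed by 1.21 on average. The Wnt list changed by 0.03 in lymphoma_7890, 0.24 in lymphoma_9250 and 0.07 in lymphoma_4936. In the Wnt list, Abcb1b, a drug efflux transporter that transports doxorubicin, had a change of 0.64 ± 0.37 and Ccnd1 of 0.60 ± 0.52. Of 16 tested Polycomb genes 12 were lower, with a mean of -0.18 ± 0.25 and a change of 0.07 in lymphoma_9250, and Cbx2 had a change of -0.67 ± 0.51. Over all genes 0 members passed, and adjusted over the list alone 1 did, Abcb1b. Camera gave adjusted p = 0.00192 for MHC class I, 0.0131 for Wnt signalling and 0.043 for Polycomb, and with an estimated correlation adjusted p = 0.572, 0.572 and 0.619. The Wnt call was lost without lymphoma_1032 (adjusted p = 0.2 in camera, with a mean of 0.22) and without the filter (0.191, with a mean of 0.08), and the Polycomb call without any of lymphoma_5783, lymphoma_7890, lymphoma_1032 or lymphoma_4936 (adjusted p from 0.0558 to 0.2 in camera, with a mean of -0.075 without lymphoma_1032). The Polycomb call was also lost without the filter, with the mean of all probe sets, with array weights and on ranks (adjusted p from 0.0566 to 0.0666 in camera). The list of H3 lysine 9 methylation and heterochromatin genes was not called (mean -0.09 ± 0.20, adjusted p = 0.215 in camera). Its mean was smaller in size without lymphoma_7890 (adjusted p = 0.846 in camera) or lymphoma_1032 (0.293), where the list changed by -0.28 and -0.32. With the preset correlation it was called, with lower signals, with the stricter filter (mean -0.13, adjusted p = 0.0408), with the mean of all probe sets (-0.15, 0.0318) and without lymphoma_9250 (-0.13, 0.0456). With an estimated correlation these calls were lost, with adjusted p = 0.643, 0.61 and 0.78. In it, Cbx5, the HP1 alpha gene, had a change of -0.50 ± 0.49 and Lmnb1, lamin B1, of -0.35 ± 0.49, which was -0.53 without lymphoma_4936, each with a lower signal in 4 of 5 lymphomas.

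Lists of lymphoid identity and cell survival were not called in camera. The means were 0.02 ± 0.36 (SD, n = 5) for B-cell identity (adjusted p = 0.412), 0.01 ± 0.57 for pro-B and pre-B cell genes (adjusted p = 0.984, with a test direction opposite to that mean), 0.13 ± 0.23 for plasma cell genes (adjusted p = 0.126), 0.06 ± 0.49 for MHC class II (adjusted p = 0.275), 0.10 ± 0.56 for interferon-stimulated genes (adjusted p = 0.114) and 0.003 ± 0.174 for the Bcl2 family (adjusted p = 0.813). Several were called, with higher signals, when 1 lymphoma was left out. Other omissions of 1 lymphoma turned the means of interferon-stimulated, MHC class II and B-cell identity genes to lower signals. Interferon-stimulated genes had a mean of 0.31 without lymphoma_7890 (adjusted p = 1.17e-06) and of 0.18 without lymphoma_9250 (0.0294), and an estimated correlation gave adjusted p = 0.469 and 0.867. MHC class II genes had a mean of 0.26 without lymphoma_1032 (0.00272), B-cell identity genes of 0.10 without lymphoma_4936 (0.0318) and plasma cell genes of 0.19 without lymphoma_9250 (0.0456), and an estimated correlation gave adjusted p = 0.717, 0.642 and 0.633. With array weights the B-cell identity (0.0275), plasma cell (0.0445) and MHC class II (0.0176) lists were called too, with adjusted p = 0.617, 0.554 and 0.616 with an estimated correlation. In the added omission of lymphoma_1032 and lymphoma_4936 camera called B-cell identity (adjusted p = 0.00336) and MHC class II (0.000104). An estimated correlation gave adjusted p = 0.556 and 0.424 there. Bcl2, the transduced gene, had a signal of 10.98 ± 0.77 untreated and 10.79 ± 1.13 with ADR. Bid, a BH3-only protein gene, had a change of 0.40 ± 0.20 and a higher signal in all 5 lymphomas.

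**Figure D1:**
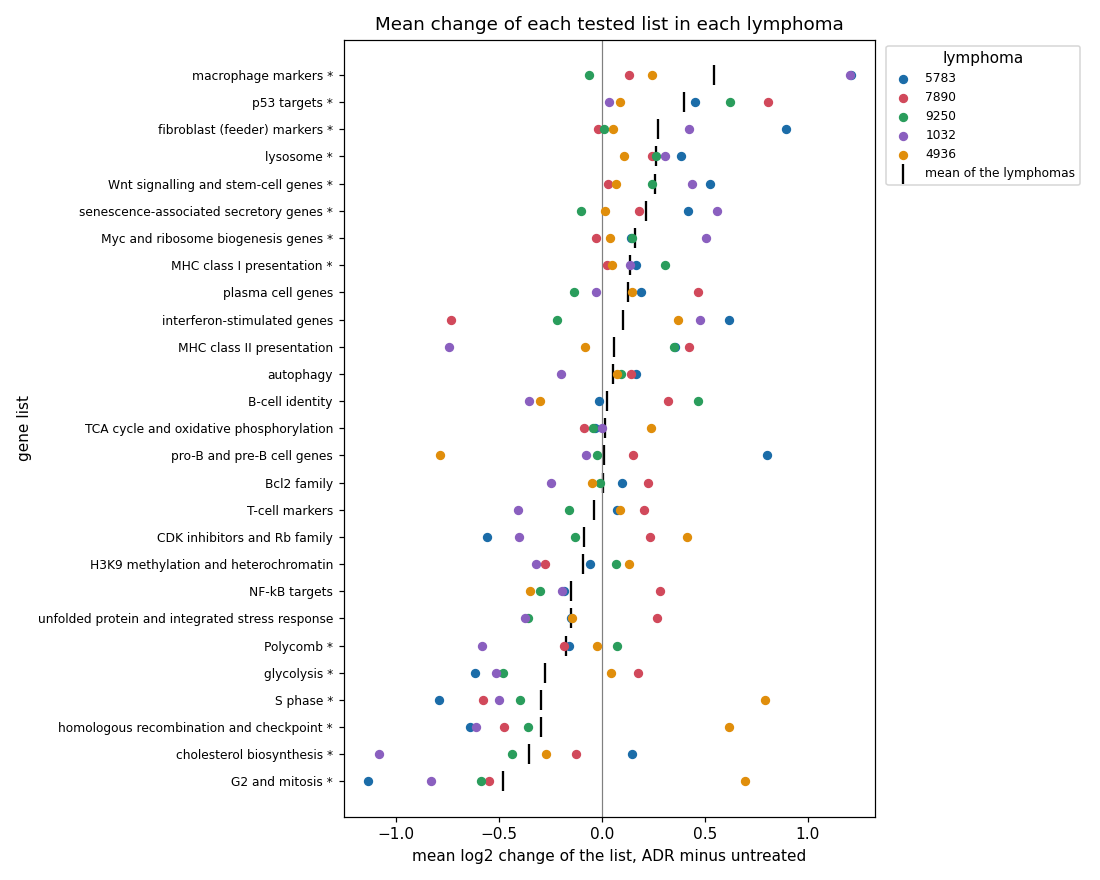
Mean log2 change (ADR minus untreated, horizontal axis) of each of the 27 tested gene lists (vertical axis), with 1 point per lymphoma and a black bar at the mean of the 5 lymphomas; a star marks lists called by camera with the preset correlation. The lysosome points lie between 0.11 and 0.38, while the G2 and mitosis points lie between -1.14 and -0.55 in 4 lymphomas and at 0.69 in lymphoma_4936.

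Across the 11472 genes, which are not independent replicates, the changes of a lymphoma and those of another correlated with a mean Pearson r of 0.10 (SD 0.16 over the 10 pairs of lymphomas, from -0.12 to 0.35). The mean was 0.20 over the pairs without lymphoma_4936, -0.06 over the pairs with it and 0.02 without lymphoma_5783. The highest value was that of lymphoma_5783 and lymphoma_1032. Without these, an omission chosen after the data were seen, the mean r was -0.01 and camera with the preset correlation called 6 lists: lysosome (adjusted p = 1.78e-06), p53 targets (1.14e-11), G2 and mitosis (0.00594, with a mean of -0.15), cholesterol biosynthesis (1.06e-07), MHC class II (0.0109) and, with lower signals, interferon-stimulated genes (0.0113). The calls of S phase, homologous recombination, glycolysis, Myc, macrophage, fibroblast, secretory, MHC class I, Wnt and Polycomb genes were lost, with adjusted p from 0.0756 to 0.989. With an estimated correlation 0 lists were called in that omission, with 0.874 as the smallest adjusted p, and 0 in each omission of 1 lymphoma, with smallest adjusted p from 0.163 to 0.717. That version of camera has few residual degrees of freedom, and fewer still in an omission. In the joint omission p53 targets stood at 0.874 too, against 1.14e-11 with the preset correlation of 0.01. Their estimated correlation was 0.31 there. Few pairs and correlation among the genes were not separated as reasons, so these losses say little about stability.

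**Figure D2:**
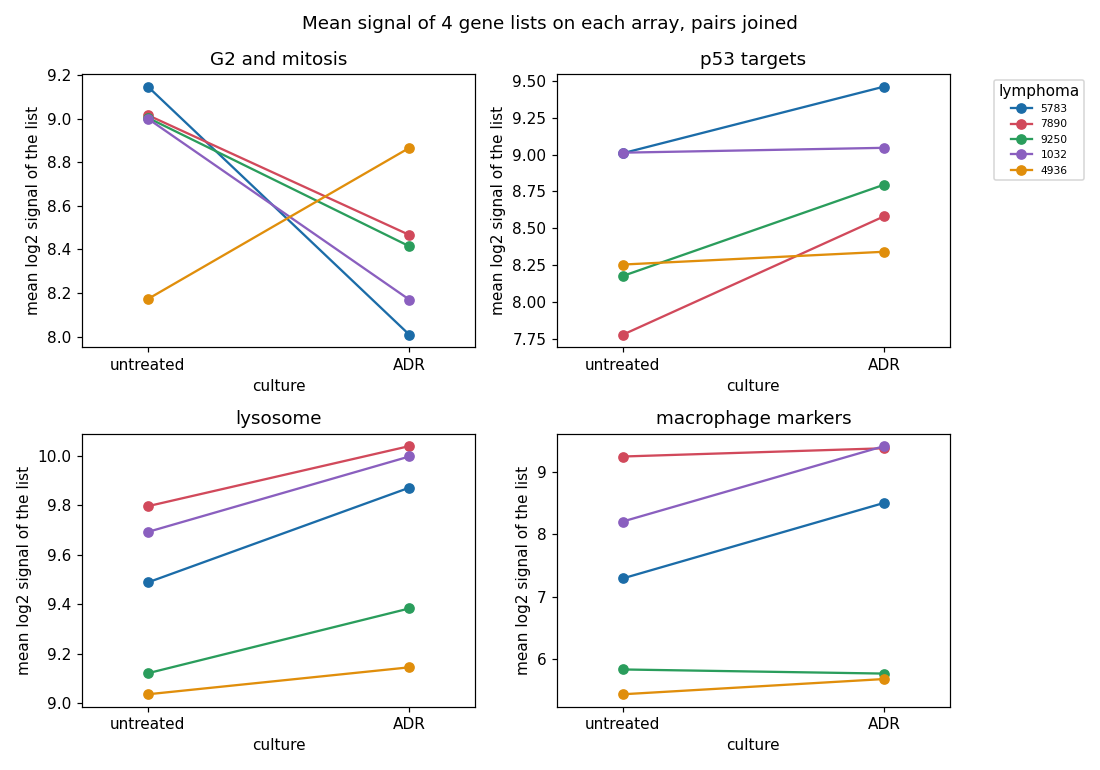
Mean log2 signal (vertical axes, which do not start at 0) of the tested members of 4 gene lists on each array, untreated and ADR (horizontal axes), with 1 line per lymphoma. In the G2 and mitosis list lymphoma_4936 went from 8.17 to 8.87 while the other 4 lymphomas started between 9.0 and 9.15 and reached 8.01 to 8.47; the lysosome lines all point up.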

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

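The swap test of lymphoma_4936 and the renormalization test of the lymphoma_1032 array were written down before their results were seen. Chosen after were the test of the macrophage markers outside the tested genes, the counts over other splits of the arrays as worded here, the tests on the G2 and mitosis level of lymphoma_4936, on G2 and mitosis genes in lymphoma_1032, on lysosome genes in lymphoma_9250 and without lymphoma_1032, and the exchange of the labels of lymphoma_4936.

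Among 131 groups of 5 values examined, 18 held a value whose gap to the next exceeded 0.71 of the range, where chance gives about 6.55. The pair of lymphoma_4936 stood apart with changes of 0.79 in the S phase list, 0.62 in the homologous recombination and checkpoint list, 0.24 in the TCA cycle and oxidative phosphorylation list, 0.83 in Cenpu and 0.26 in Gm31718. That of lymphoma_7890 stood apart with changes of 0.28 in NF-kB targets, 1.36 in Cdkn1a and -0.10 in Psmb10. That of lymphoma_5783 did so with -3.01 in Cdkn2a and 0.51 in Ctnnb1, and lymphoma_1032 with -0.20 in the autophagy list, 1.02 in Cad, and Il6 signals of 10.99 untreated and 11.94 with ADR. The arrays of lymphoma_1032 also stood apart in their values as a whole: the ADR array had a mean of 4.96, a median of 4.15 and a maximum of 15.63, and the untreated array had a maximum of 14.45.

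The pattern most in need of a second look is that of the division lists in lymphoma_4936, whose means went up with ADR while they went down in the other 4 lymphomas. Not every member followed, as Cenpa changed by -0.43 in lymphoma_4936. If the arrays carry the right labels, a low start of the untreated culture alone was not enough for the G2 and mitosis list. The ADR array of lymphoma_4936 lay 0.40 above the highest other ADR array in the mean G2 and mitosis level, against an SD of 0.21 among those arrays. For the other division lists a low start stays open. In S phase the level on that array was 8.72, against 8.63 on the highest other ADR array. In homologous recombination it was 7.17, within the 6.53 to 7.35 of the other ADR arrays. If the arrays of lymphoma_4936 were swapped, these comparisons say nothing. A weak p53 response as the reason stays open: only lymphoma_1032 also had a p53 list change near 0, at 0.03, and a G2 and mitosis change of -0.83 in 1 lymphoma decides nothing. Swapped arrays of lymphoma_4936 could not be told apart from a true difference. Of the 100 genes with the highest t in limma without lymphoma_4936, division and repair lists left out, 51% were higher in lymphoma_4936. Of the 100 with the lowest t 15% were lower there. Division genes outside the fixed lists may be among these 100, so the 15% may restate the division pattern. Of all tested genes outside the division and repair lists 56.1% were higher and 43.9% lower. With the labels of lymphoma_4936 exchanged 1368 genes had an unadjusted p below 0.05 in limma, against 973 as labelled. The mean r of the changes was then 0.14, against 0.10. The camera calls of p53 targets and lysosome were weaker when exchanged but still past the threshold. Their adjusted p were 1.69e-08 and 3.66e-09, against 2.72e-10 and 1.52e-11 as labelled. A drug response of its own in lymphoma_4936 remains open as well, and no test here separates these.

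The tested macrophage and fibroblast markers were higher on average with ADR in lymphoma_5783 and lymphoma_1032. The unusual distribution of the lymphoma_1032 array was not the reason for the macrophage change there. The tested macrophage markers still changed by 1.26 in lymphoma_1032 after another quantile normalization. The fibroblast markers of that lymphoma were not tested in this way, nor was array quality. More RNA from macrophages in these ADR cultures stays open. Lyz1 reached 14.24 in lymphoma_5783 and 14.63 in lymphoma_1032 with ADR. Its level was also high in lymphoma_7890, at 13.9 untreated and 14.08 with ADR, where the macrophage list changed by 0.13. The 5 macrophage markers that were not among the tested genes had a mean change of -1.83 in lymphoma_5783, with C1qa going from 6.82 to 3.91, C1qb from 7.55 to 5.14 and Mrc1 from 7.64 to 4.70, and of -0.32 in lymphoma_1032, where their untreated mean of 3.10 was too low to decide. Without lymphoma_5783 and lymphoma_1032 the secretory list had a mean of 0.031, so that a source of its change in lymphoma cells cannot be separated from the other cells with these arrays.

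The lysosome list was higher in all 5 lymphomas. Macrophage RNA as a source stays open: only in lymphoma_9250 was the macrophage list change not above 0, at -0.07, and a lysosome change of 0.26 in 1 lymphoma decides nothing. The lymphoma_1032 array was not the source, since the mean without it was 0.25 ± 0.11. A response of the lymphoma cells may be another explanation and was not tested. If the arrays of lymphoma_4936 were exchanged, the list would be lower there with ADR.

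For the 0 genes past the threshold, at 2-fold or more too, the 100 drawn splits of the arrays out of 126 decide nothing, since all 100 give at least 0; the highest gave 2. Chance cannot be excluded for the count at an unadjusted p or for the lists. At an unadjusted p below 0.05, 12 of the 100 splits gave 973 genes or more, the highest of the others 1733. Of these 12, 8 part 3 of the pairs and 3 part 1. For the 14 lists called by camera with the preset correlation, 29 of the 100 splits gave as many, the highest of the others 18. Of these 29, 24 part 3 of the pairs. Of the 14 drawn splits that part all 5 pairs, 1 gave 973 genes or more, the real one, with 670 as the highest of the others, and 5 gave 14 lists or more, with 15 as the highest of the others; these splits are too few for a share under 0.05. The exchange of the labels of lymphoma_4936, which gave 1368 genes and 15 lists with the preset correlation and 0 with an estimated one, also parts all 5 pairs and was not among those drawn. With the lymphoma as a block, splits that part 3 or 1 of the pairs take their contrast from those pairs alone. The other pairs then add their ADR changes to the residual spread. Several of these splits gave identical counts, so the shares over all 100 splits are not rates under chance.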

How the results depend on the processing

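The alternatives fry, the joint omission of lymphomas and the other settings and omissions with an estimated correlation were chosen after the data were seen; the others were planned. The count of 0 genes past the threshold held under every alternative run with limma, at 2-fold too. Without the replicate block of paired arrays it was also 0, with 262 instead of 973 genes at an unadjusted p below 0.05, and 13 instead of 14 lists called. When 1 lymphoma was left out the unadjusted count ranged from 551 (without lymphoma_5783) to 1446 (without lymphoma_4936). It was 499 without lymphoma_5783 and lymphoma_1032. The number of lists called was 0 with an estimated correlation in camera and 0 with fry, where lysosome had the smallest adjusted p, 0.0769. It was also 0 with an estimated correlation in each omission of 1 or 2 lymphomas, without the filter, with the stricter filter, with the mean of all probe sets, with another quantile normalization, with centred arrays and with array weights. With so few pairs that version of camera can hardly call any list, but it also allows for correlation among the genes. With all lymphomas the estimated correlation was 0.85 in S phase, 0.81 in G2 and mitosis and 0.10 in lysosome genes. The small adjusted p of the main setting thus rest on the low preset of 0.01. Few pairs and correlation were not separated as reasons, so these counts of 0 say little about stability. With the preset correlation the number was 6 without lymphoma_5783 and lymphoma_1032, where fewer arrays were used, and from 10 to 17 when 1 lymphoma was left out. In that joint omission the fibroblast list, with a mean of 0.013 and an adjusted p of 0.989, and the interferon-stimulated list, with a mean of -0.20 and an adjusted p of 0.0113, took the opposite direction in camera; the cause was not tested. Of all results for single lists, 57 lost a call, 22 gained one and 406 stayed on their side of the threshold; 25 of these 406, all under another fit, changed sign with no call in either setting. The 148 results for single genes kept their side of the threshold. With the settings chosen before the data were examined the fibroblast list change ranged from 0.12 to 0.46, the 3' to 5' change from 0.021 to 0.054 and the mean correlation of the lymphomas from 0.024 to 0.20, each with its sign kept. Without lymphoma_5783 and lymphoma_1032 they were 0.013, 0.070 and -0.014, and without lymphoma_1032 and lymphoma_4936 0.29, 0.034 and 0.22. The exact test of 5 pairs cannot pass the threshold and says nothing about stability. Signals near the background of the arrays are compressed, and a gene with a higher signal in only 1 or 2 lymphomas also failed the filter; the macrophage mean was 0.30 without it.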

Other observations

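The lymphomas differed from each other in both conditions, in genes named here after their values were seen. Cdkn2a had a signal of 8.66 untreated and 8.46 with ADR in lymphoma_4936, and of 1.96 and 1.87 in lymphoma_1032. The untreated array of lymphoma_1032 had signals of 11.03 for Il1b, 13.40 for the chemokine gene Ccl3, 10.43 for the collagenase gene Mmp13, 12.76 for Lcn2 and 10.85 for Cdkn2b, which encodes the CDK inhibitor p15. In the other untreated lymphomas these genes lay at most at 7.99, 9.20, 4.78, 7.80 and 6.70. Rag1, of immunoglobulin gene recombination, ranged from 1.34 in lymphoma_1032 to 7.66 in lymphoma_4936 without treatment. The macrophage list had a mean signal of 9.24 in untreated lymphoma_7890 and of 5.44 in untreated lymphoma_4936, so that its level differed between lymphomas by more than it changed with ADR.

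Several lists that were not called moved in opposite directions in different lymphomas, and these differences were not tested. Interferon-stimulated genes had a mean change of 0.62 in lymphoma_5783 and of -0.73 in lymphoma_7890, with Rsad2 going from 9.09 to 8.23 in the latter and from 7.65 to 9.08 in lymphoma_1032. MHC class II genes had a mean change of -0.75 in lymphoma_1032 and of 0.35 to 0.42 in lymphoma_5783, lymphoma_7890 and lymphoma_9250. Pro-B and pre-B cell genes had a mean change of 0.80 in lymphoma_5783, where Igll1, the surrogate light chain gene, went from 6.30 to 10.23, and of -0.79 in lymphoma_4936. Prdm1, the plasma cell regulator Blimp-1, went from 10.44 to 8.25 in lymphoma_1032.

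The probe sets that were unnamed or carried several genes were tested in the same fit of 22803 probe sets: 0 of 2705 passed the threshold in limma, and 207 had an unadjusted p below 0.05.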
